A study of Mus musculus with 6 samples.

How the data were processed

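The data were RNA-seq libraries of sorted mouse cap mesenchyme at embryonic day 18.5, 3 from Six2-Cre conditional Dnmt1 heterozygotes and 3 from homozygous knockouts, prepared with an ultra low input protocol and sequenced on an Illumina HiSeq2000, per the labels' protocols. The authors deposited 1 table per library with a row per transcript. Per the file headers and the submitters' processing notes, each table holds kallisto output: estimated counts (expected counts that need not be whole), TPM (abundance scaled by transcript length and library total), and the effective length of each transcript in bases, a value deposited for scaling and used here only as an offset. The genome build mm10 is named in the submitters' processing notes. The kallisto version, the annotation release behind the index, read trimming, read length and the strandedness of the library kit are not given in the sources used here, so reads from a gene and an antisense partner cannot be told apart. Groups were taken from the sample titles and replicates from their numbers. The labels state n = 3 and do not say whether each library came from a separate embryo or litter, so p-values measure only the spread between these samples.

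Each file listed the same 96626 transcripts. GENCODE vM1, annotated on NCBIM37, paired 74519 of them with 26567 genes, and these held 92.4% to 92.82% of the counts. The other 22107 transcripts (7.18% to 7.6% of counts) entered the transcript test only. Coordinates are those of NCBIM37, not of the build the submitters name. Estimated counts were summed per gene and rounded to whole numbers. Gene symbols are those of the annotation, and list members were matched through current or older symbols.

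The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, limma 3.58.1, R 4.3.3) with TMM normalisation, filterByExpr with default settings and robust dispersions, comparing knockout with heterozygous without covariates, and with Benjamini-Hochberg adjustment over the 16989 genes kept, at 0.05. Standard errors are those of the fitted log2 fold change. Normalised CPM values use the TMM library sizes, and their spread is given as SD over 3 libraries. The biological coefficient of variation was 0.21. For a gene at 0 in all libraries of a group, fold changes are lower bounds computed against 3 counts in each library of that group, and with 1 to 3 counts a ratio with an exact 95% binomial counting interval is given; both cover counting error only. No pair of libraries agreed within sampling noise: the chi-square per degree of freedom over genes was between 14.26 and 43.78 within groups and at least 266.55 between groups.

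Before the data were examined, 21 gene lists, the rules for naming genes, the rule for genes near 0 and the alternative analyses were fixed, apart from those said to be added later. Lists with at least 5 tested members, 20 of the 21, were compared with all other genes by limma's camera with a preset correlation of 0.01 and again with an estimated correlation, and each list was tested against no change, not against other genes, with limma's fry; the list of sex-linked genes was too small and was used to read the sex of the embryos, taken as male above 50 CPM of Y-linked genes. Genes are named if they are Dnmt1, Dnmt3a, Dnmt3b or Uhrf1, if they are among the 12 largest rises or 8 largest falls of called protein-coding genes with a mean of at least 1 CPM and no overlap between groups, predicted genes left out, or if they have 1 of the 4 smallest p in a fixed list; other names are said to have been chosen after their values were seen. Some genes that the rule takes are not reported here. Alternatives were DESeq2 1.42.0 (its test, and its size factors within edgeR), library totals without composition normalisation, other filters, limma voom, transcript-length offsets, limma on log2(TPM + 1) and log2(TPM + 0.1) for genes with a mean TPM of at least 1 and log2(TPM + 1) without that filter, the replicate number as a block, protein-coding genes only, chromosomes X and Y left out, non-robust dispersions and each library left out in turn. Sex as a covariate and removal of repeat-containing transcripts were added after the data were seen, and the result without knockout replicate 1 was read again for its markers of other cell types.

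To find repeat-containing transcripts, 31-mers of the 74509 paired transcripts long enough were counted in the NCBIM37 genome from a fixed sample of 1 in 8, and a transcript was called repeat-containing when at least 10% of its sampled 31-mers occurred at least 10 times, which held for 2838. Single-copy genes are those whose leading transcript, or for promoter CpG every transcript, had sampled 31-mers with a median of 1 copy. No annotation of repeat families was used here. The ratio of observed to expected CpG sites was read from the same genome, over 500 bases on each side of the annotated 5' end of the gene. The tests were checked on simulated data made from the real means, library sizes and dispersions with 200 of 16989 genes changed between knockout and heterozygous. The edgeR test recovered 40% of 1.5-fold, 70% of 2-fold and 97.5% of 4-fold increases and 32.5% of 1.5-fold and 75% of 2-fold decreases, and 5.3% of its calls were false. A planted list was found and 0 unchanged lists were called. The simulation took no correlation between genes from the data, so it does not check the list calls against such correlation. Permutation and exact tests used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.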

Results

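RNA was sequenced from cap mesenchyme, the cells around the ureteric tips of the embryonic kidney that hold the nephron progenitors, sorted from mouse kidneys at embryonic day 18.5. A Cre recombinase driven by Six2, a transcription factor of these progenitors, deleted conditional alleles of Dnmt1, the enzyme that copies DNA methylation onto new strands at replication. There were 3 libraries with 1 deleted allele, called heterozygous here, and 3 libraries with both alleles deleted, called knockout. Kallisto estimated counts summed to between 46741667 and 61585484 per library, and 92.4% to 92.82% of them fell on transcripts that could be paired with a gene. At that depth 3 counts corresponded to between 0.052 and 0.069 CPM (counts scaled by library size), a limit that covers counting error only. The first principal component of log2 CPM held 64.1% of the variance and separated the 3 heterozygous libraries (-69.26 to -55.17) from the 3 knockout libraries (49.86 to 70.05). Summed counts of 4 Y-linked genes were 332, 9.64 and 268 CPM in heterozygous replicates 1 to 3 and 7.66, 168 and 9.83 CPM in knockout replicates 1 to 3, so each group held libraries of both sexes.

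Dnmt1 itself was measured first. Its level was 40.04, 52.4 and 51.7 CPM in the 3 heterozygous libraries and 20.9, 18.6 and 14.9 CPM in the 3 knockout libraries. The means were 48.1 ± 6.95 and 18.1 ± 3.02 CPM (SD, n = 3 each), a log2 fold change of -1.41 ± 0.15 (SE; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.000264). The gene lies on chromosome 9 from 20711650 to 20757317 (NCBIM37), and its counts covered the whole transcript, including any part that the deletion left in place. Its knockout values fell from replicate 1 to replicate 3, as did the means of the endothelium markers given below. Whether cells of other types added to the remaining signal was not tested. The transcripts of the other methyltransferases and of Uhrf1, the protein that brings Dnmt1 to hemimethylated DNA, did not pass the test. Dnmt3a had a log2 fold change of -0.08 ± 0.08, Dnmt3b of 0.12 ± 0.17 and Uhrf1 of 0.23 ± 0.08 (SE; edgeR, Benjamini-Hochberg adjusted p = 0.577, 0.720 and 0.116), and the sign for Dnmt3a turned with a transcript length offset and that for Dnmt3b with library totals or TPM.

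The knockout cap mesenchyme contained transcripts of genes normally used in germ cells that were absent or nearly absent from the heterozygous cells. Dazl, an RNA-binding protein of germ cells chosen here after its values were seen and not tested without each library in turn, went from 0.139 ± 0.186 to 268 ± 33.8 CPM (SD, n = 3 each), and Tex19.1, a germline defence gene against transposable elements, from 0.126 ± 0.0389 to 48.1 ± 7.12 CPM. Most genes that fell did so by smaller amounts. Among 16989 genes tested, 836 were higher and 327 lower in the knockout (edgeR quasi-likelihood test at a Benjamini-Hochberg adjusted p of 0.05), and 71.9% of the calls were higher. More than 2-fold changes were found for 586 of the higher and 52 of the lower genes, and more than 16-fold changes for 271 and 6. The median fitted log2 fold change was 1.94 over the higher genes and -0.59 over the lower genes; for genes at 0 in a whole group these fitted values depend on the prior count and are no bound. The groups did not overlap for 4926 genes, 29.0% of those tested, where chance gives 10%. With DESeq2 the counts were 1346 and 586, and without knockout replicate 2 they were 526 and 116. The lower genes were 170 without heterozygous replicate 2, 171 without heterozygous replicate 3 and 162 with sex as a covariate, an analysis added after the data were seen. With repeat-containing transcripts left out, also added later, 735 genes were higher and 313 lower. Scaling to library totals alone moved the median of all genes to -0.17 and gave 731 higher and 1883 lower genes. Limma on log2(TPM + 1) gave 442 and 660 with a filter on mean TPM (median -0.13) and 542 and 365 without it (median -0.04).

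**Figure D1:**
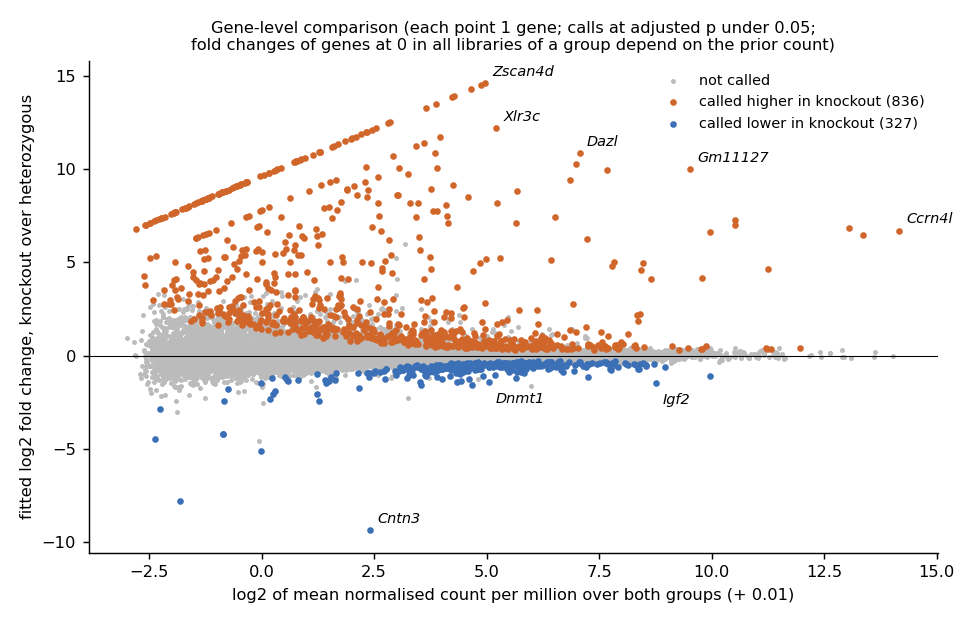
Fitted log2 fold change of knockout over heterozygous (vertical axis) against the log2 of the mean CPM over both groups plus 0.01 (horizontal axis) for the 16989 tested genes, 1 point each, with calls in colour. The 836 genes called higher reach far larger fold changes than the 327 called lower, and the straight upper edge holds genes at 0 in all heterozygous libraries, whose fitted fold change depends on the prior count.

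Genes that were silent in the heterozygous group and present in the knockout were counted by a fixed rule. At no more than 3 counts over the 3 libraries of the silent group and at least 10 in every library of the other, 159 genes were switched on in the knockout and 3 were switched off (2-sided exact binomial p = 2.42e-43 over genes, which are not independent). The 159 included 138 protein-coding genes, 49 genes on chromosome X and 18 members of the germline list. Only 84 of the 159 were single-copy genes. Some entries, such as Gm5128 and Gm7903 on chromosome X, had the same estimated counts in every library. The 159 are therefore fewer separately measured genes than their number says. The 3 genes switched off were Cntn3, Ccl27b and Lrrfip2. Chromosome X also stood out among all calls, with 101 of 722 tested genes higher against 735 of 16267 on the other chromosomes (odds ratio 3.44; 1-sided Fisher's exact p = 5.67e-22). Of the same genes, 23 on chromosome X and 304 on the others were lower.

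Named by the fixed rule, the protein-coding genes with the largest fitted log2 fold changes were germline genes or members of multicopy families. For genes at 0 this ranking depends on the prior count, so Rhox2a, with a count ratio of 3000, stands below Rhox2c. Zscan4d and Zscan4e on chromosome 7 are zinc finger genes known from the 2-cell embryo. They were at 0 in all heterozygous libraries and at 62.2 ± 11.2 and 29.1 ± 6.48 CPM in the knockout (SD, n = 3). That made them at least 1060-fold and at least 497-fold higher against 3 counts in each heterozygous library. The deubiquitinase genes Dub3 and Dub1a, also on chromosome 7, were at least 239-fold and at least 198-fold higher. Mov10l1, an RNA helicase of the piRNA pathway, was at 25.1 ± 1.70 CPM in the knockout (at least 430-fold higher), and Tex101 (at least 247-fold), Asz1 (at least 158-fold) and Fkbp6 (at least 146-fold), all of them germline genes, were likewise at 0 in every heterozygous library. On chromosome X, Mageb10-ps, Rhox2b and Rhox2c were at least 136-fold, at least 123-fold and at least 110-fold higher. Xlr3c on chromosome X had 2.6 estimated counts over the heterozygous group against 11077 in the knockout, a ratio of 4420 with a 95% counting interval of 1310 to 18600. Adjusted p over these 12 genes lay between 8.69e-10 and 3.56e-06 (edgeR quasi-likelihood test, Benjamini-Hochberg), and all 12 calls held without each library in turn. The Zscan4, Dub, Rhox2 and Xlr3 genes are near-identical copies, so how kallisto divided reads among the members of each family is uncertain.

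Among the fixed lists, 6 of 20 tested were higher and 2 lower in the knockout (limma's camera at a Benjamini-Hochberg adjusted p of 0.05), with 10 higher without knockout replicate 3 and 4 higher without knockout replicate 1 or heterozygous replicate 1. Only 1 list was lower without knockout replicate 1 or 3. Other splits of the 6 libraries into 3 and 3 called up to 12 lists, so the 8 calls of the real split do not set it apart. The medians of these 8 lists kept their sign under library totals and TPM, whereas those of p53 targets, proliferation, committed nephron, imprinted, Wnt target and hypoxia genes turned below 0 under library totals. The median log2 ratio of all tested genes also moved, from -0.002 to -0.161 under library totals and -0.126 under TPM. That shift takes medians just above 0 below it and does not test the 2 lower lists. Germline genes with methylation-dependent promoters had the highest median of the 8 called lists. Of 71 members tested, 55 rose, none fell and 16 did not pass, and 60 rose when adjusted over the list alone. Their median log2 fold change was 5.31, or 4.21 with members at 0 placed at the bound that 3 counts per library allow (limma's camera, Benjamini-Hochberg adjusted p = 3.51e-129). It was the only list whose call held with an estimated correlation (adjusted p = 0.0104, limma's camera). Gpat2, an acyltransferase of the piRNA pathway, rose from 1.996 ± 0.357 to 76.7 ± 5.83 CPM (SD, n = 3 each), a log2 fold change of 5.25 ± 0.15 (SE; edgeR, Benjamini-Hochberg adjusted p = 6.01e-09). Tex19.1 rose by 8.52 ± 0.22 on the log2 scale and Dazl by 10.86 ± 0.49 (SE). Rhox2a, a homeobox gene on chromosome X, was at 29.0 ± 2.09 CPM in the knockout and had a count ratio of 3000 with a 95% counting interval of 623 to 18600. The list means were 0.850, 0.729 and 0.784 on the log2(CPM + 1) scale in the heterozygous libraries and 3.08, 3.10 and 2.92 in the knockout libraries.

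**Figure D2:**
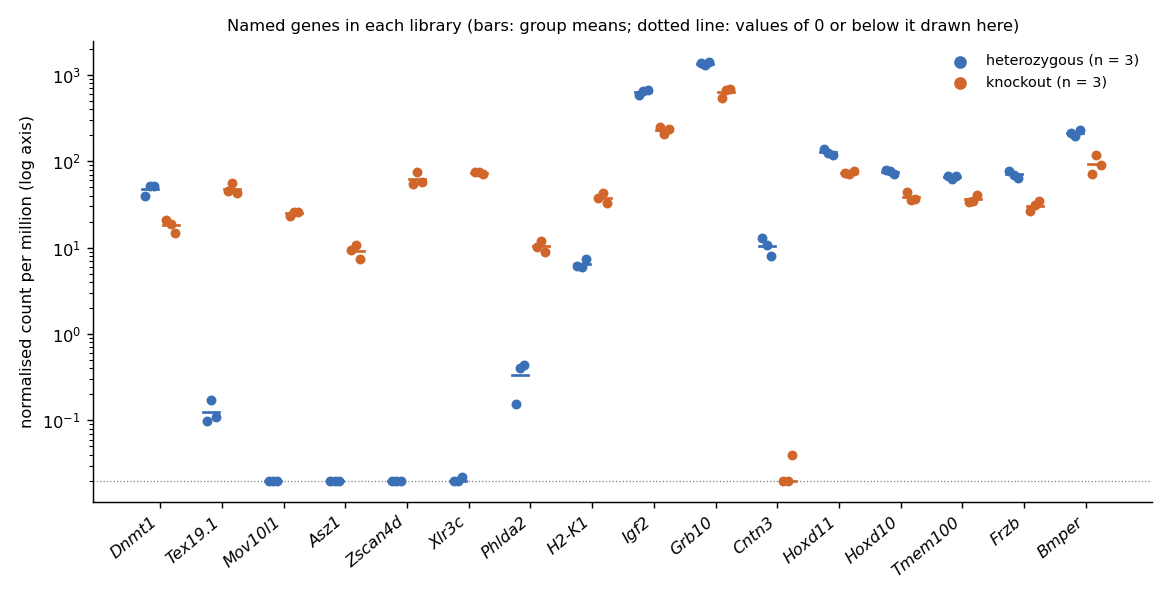
Normalised CPM on a log axis for named genes in each of the 3 heterozygous (blue) and 3 knockout (orange) libraries, with group means as bars; values of 0 or under the dotted line are drawn on it. Mov10l1, Asz1 and Zscan4d lie at 0 in every heterozygous library, while Dnmt1, Igf2 and Grb10 fall by less than 3-fold.

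Interferon and viral defence genes were higher in the knockout, with 12 of 59 members called, none lower and 47 not passing (25 adjusted over the list alone). The list had a median log2 fold change of 0.71 (limma's camera, Benjamini-Hochberg adjusted p = 5.89e-06), and the adjusted p = 0.603 with an estimated correlation. H2-K1, a class I histocompatibility molecule, rose from 6.47 ± 0.782 to 37.7 ± 4.797 CPM (SD, n = 3 each; log2 fold change 2.54 ± 0.14, SE; edgeR, Benjamini-Hochberg adjusted p = 1.35e-06). Ifit2, an interferon-induced antiviral protein, rose by 0.76 ± 0.12 and Lgals3bp by 0.91 ± 0.15 on the log2 scale (SE). The list means were 3.19, 2.97 and 2.55 in knockout replicates 1 to 3 and between 2.25 and 2.30 in the heterozygous libraries. Endothelium markers had the same order over the knockout libraries, at 3.94, 2.92 and 2.16, with 1.98 to 2.17 in the heterozygous libraries. Without knockout replicate 1 the interferon list had an adjusted p of 0.000173 (limma's camera, Benjamini-Hochberg).

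Immediate early and dissociation stress genes rose for 9 of 29 members, none fell and 20 did not pass (13 adjusted over the list alone). The list's median log2 fold change was 0.36 (limma's camera, Benjamini-Hochberg adjusted p = 0.00294), with an adjusted p = 0.603 with an estimated correlation. Atf3, a stress-induced transcription factor, rose from 18.2 ± 3.34 to 69.6 ± 23.1 CPM (SD, n = 3 each), and Egr2, an early growth response factor, by 1.26 ± 0.23 on the log2 scale (SE). The call for Atf3 was lost without heterozygous replicate 1, and that for Egr2 without heterozygous replicate 1 or 2 (edgeR, Benjamini-Hochberg adjusted p up to 0.0576 and 0.0828). The list means were 6.00, 5.96 and 5.77 in knockout replicates 1 to 3 and 5.46 to 5.61 in the heterozygous libraries. Endothelium markers had 3.94, 2.92 and 2.16 against 1.98 to 2.17.

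Among p53 targets 5 of 41 members rose, none fell and 36 did not pass (7 adjusted over the list alone), and the list itself did not pass (limma's camera, Benjamini-Hochberg adjusted p = 0.0805, with 0.0312 without knockout replicate 3 and 0.0338 with sex as a covariate). Cdkn1a, the cell cycle inhibitor p21, rose from 52.9 ± 3.98 to 103 ± 16.5 CPM (SD, n = 3 each; edgeR, Benjamini-Hochberg adjusted p = 0.000597), and Ddit4l, an inhibitor of mTOR signalling, rose by 1.17 ± 0.15 on the log2 scale (SE). Pmaip1, a pro-apoptotic BH3-only protein, rose by 2.62 ± 0.48, and its call was lost without knockout replicate 2 (edgeR, Benjamini-Hochberg adjusted p = 0.0604). Proliferation genes were nearly balanced, with 1 of 40 higher, 1 lower and 38 not passing and a median log2 fold change of 0.02 (limma's camera, Benjamini-Hochberg adjusted p = 0.767). The calls for Kif20a (0.34 ± 0.07 on the log2 scale, SE) and Rrm2 (-0.31 ± 0.08) were lost without at least 4 of the 6 libraries in turn (edgeR, Benjamini-Hochberg adjusted p up to 0.0799 and 0.172).

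Nephron progenitor genes were lower as a list. Of 41 members tested, 7 fell, 2 rose and 32 did not pass (12 and 3 adjusted over the list alone), with a median log2 fold change of -0.23 and a mean of -0.08 (limma's camera, Benjamini-Hochberg adjusted p = 0.00553). The call was lost with an estimated correlation (adjusted p = 0.603) and without knockout replicate 1 (adjusted p = 0.0697; limma's camera). Hoxd11, a homeobox gene, fell from 128 ± 10.3 to 73.9 ± 2.73 CPM and Hoxd10 from 75.4 ± 3.65 to 38.9 ± 5.11 CPM (SD, n = 3 each). Their log2 fold changes were -0.79 ± 0.08 and -0.96 ± 0.10 (SE; edgeR, Benjamini-Hochberg adjusted p = 0.000233 and 0.000287). Hoxa10 had a log2 fold change of -0.64 ± 0.08 and Tmem100 of -0.87 ± 0.10 (SE). The list means were 5.56, 5.72 and 5.69 in knockout replicates 1 to 3 and 5.78 to 5.85 in the heterozygous libraries, while endothelium markers had 3.94, 2.92 and 2.16 against 1.98 to 2.17. Other called members, named after their values were seen and not tested without each library in turn, included Wt1 (-0.74 ± 0.13), Nr2f2 (-0.60 ± 0.09), Cited1 (-0.91 ± 0.19) and Capn6 (0.53 ± 0.11). Six2, the gene whose promoter drove Cre, was at 113 ± 11.99 CPM in the heterozygous and 92.0 ± 15.5 CPM in the knockout libraries (SD, n = 3 each) and did not pass (edgeR, Benjamini-Hochberg adjusted p = 0.230).

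Genes of the committed and early nephron moved in both directions, with 3 of 36 higher, 2 lower and 31 not passing (3 higher and 3 lower adjusted over the list alone), and the list did not pass (limma's camera, Benjamini-Hochberg adjusted p = 0.965). Frzb, a secreted Wnt inhibitor, fell from 70.4 ± 6.23 to 30.7 ± 4.15 CPM (SD, n = 3 each; edgeR, Benjamini-Hochberg adjusted p = 0.000112). Bmper, a BMP-binding protein, had a log2 fold change of -1.17 ± 0.17 (SE), and its call was lost without heterozygous replicate 1 (edgeR, Benjamini-Hochberg adjusted p = 0.0649). Pax8, a transcription factor of the early nephron, rose by 0.57 ± 0.09 and Wfdc2, a secreted epithelial protein, by 1.15 ± 0.15 on the log2 scale (SE). Podocyte genes were lower as a list, with 4 of 29 members lower, 1 higher and 24 not passing (5 lower and 1 higher adjusted over the list alone) and a median log2 fold change of -0.26 (limma's camera, Benjamini-Hochberg adjusted p = 0.0234). With an estimated correlation the adjusted p = 0.603, without knockout replicate 3 it was 0.0548 and without knockout replicate 1 it was 0.000299 (limma's camera). The list means were 3.94, 3.63 and 3.58 in knockout replicates 1 to 3 and 3.96 to 4.002 in the heterozygous libraries, so replicate 1 lay close to the heterozygous level. Endothelium markers had 3.94, 2.92 and 2.16 against 1.98 to 2.17. Foxc2, a forkhead transcription factor, had a log2 fold change of -0.78 ± 0.16, while Cldn1, a tight junction protein, rose by 0.61 ± 0.12 (SE). The call for Foxc2 was lost without heterozygous replicates 1 or 2 or knockout replicate 2, and that for Cldn1 without heterozygous replicate 3 (edgeR, Benjamini-Hochberg adjusted p up to 0.0900 and 0.0661).

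Wnt/beta-catenin targets did not pass as a list (1 of 22 higher, none lower, 21 not passing; limma's camera, Benjamini-Hochberg adjusted p = 0.758). Wnt4, a Wnt ligand that starts nephron formation, was at 108 ± 15.1 CPM in the heterozygous and 80.3 ± 11.6 CPM in the knockout libraries (SD, n = 3 each; edgeR, Benjamini-Hochberg adjusted p = 0.0811). The called member of the list was Sp5, at 1.10 ± 0.24 on the log2 scale (SE), a call lost without 5 of the 6 libraries in turn, all but knockout replicate 3 (edgeR, Benjamini-Hochberg adjusted p up to 0.0853). Hypoxia and glycolysis genes (1 of 28 higher, none lower, 27 not passing) and DNA methylation machinery genes (1 of 21 lower, none higher, 20 not passing) did not pass either (limma's camera, Benjamini-Hochberg adjusted p = 0.506 and 0.142). The member of the hypoxia list that rose was Car12, a carbonic anhydrase, from 33.7 ± 3.85 to 63.4 ± 6.75 CPM (SD, n = 3 each), and the member of the methylation list that fell was Dnmt1.

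Markers of cells outside the cap mesenchyme were higher in some knockout libraries than in others. Endothelium markers rose for 2 of 21 members, none fell and 19 did not pass (4 adjusted over the list alone), with a median log2 fold change of 1.54 (limma's camera, Benjamini-Hochberg adjusted p = 0.0135). Ureteric bud and collecting duct markers rose for 2 of 34, none fell and 32 did not pass (2 adjusted over the list alone), with a median of 0.99 (limma's camera, Benjamini-Hochberg adjusted p = 0.0383). Both calls were lost with an estimated correlation (adjusted p = 0.878 for each), without knockout replicate 1 (adjusted p = 0.0683 and 0.232) and without heterozygous replicate 1 (adjusted p = 0.116 and 0.201; limma's camera). The collecting duct call was also lost with sex as a covariate and with the replicate number as a block (adjusted p = 0.0551 and 0.0628, limma's camera). On the log2(CPM + 1) scale the collecting duct list had means of 3.40, 2.63 and 2.04 in knockout replicates 1 to 3 against 1.86 to 2.17 in the heterozygous libraries. The stroma list had 5.32, 4.63 and 4.36 against 4.25 to 4.41. Proximal tubule markers followed the same order at 2.92, 1.87 and 1.43, against 1.65 to 1.99. Emcn, an endothelial sialomucin, was at 5.70 ± 0.571 CPM in the heterozygous and 28.4 ± 16.1 CPM in the knockout libraries (SD, n = 3 each; edgeR, Benjamini-Hochberg adjusted p = 0.0425), and its call was lost without any heterozygous library or without knockout replicate 2 (adjusted p up to 0.173). Lyve1, a hyaluronan receptor of lymphatic endothelium, had a log2 fold change of 1.78 ± 0.44 (SE), and its call was lost without each library in turn except knockout replicate 3 (edgeR, Benjamini-Hochberg adjusted p up to 0.154). Trp63, a transcription factor of stratified epithelia, rose by 2.62 ± 0.35 and Ret, the receptor of the ureteric tip, by 3.03 ± 0.53 (SE), and the call for Ret was lost without heterozygous replicate 3 (edgeR, Benjamini-Hochberg adjusted p = 0.0602).

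Stroma and mesenchyme markers did not pass as a list (2 of 34 higher, 1 lower, 31 not passing; median log2 fold change 0.55; limma's camera, Benjamini-Hochberg adjusted p = 0.142, with 0.0484 and 0.0011 without knockout replicates 2 and 3). Crabp1, a retinoic acid binding protein, rose by 1.36 ± 0.24 and Cspg4, a pericyte proteoglycan, had a log2 fold change of -0.90 ± 0.12 (SE). Lum rose by 1.82 ± 0.38, a call lost without any heterozygous library or without knockout replicate 2 (edgeR, Benjamini-Hochberg adjusted p up to 0.175). Immune cell markers rose for 4 of 20 members, none fell and 16 did not pass (limma's camera, Benjamini-Hochberg adjusted p = 0.0805 for the list, and 0.0446 without knockout replicate 3). These were Lyz2, Mrc1, Cd79a and Laptm5, with log2 fold changes of 1.45, 1.27, 1.39 and 0.93, and each lost its call without at least 3 of the libraries, left out in turn (edgeR, Benjamini-Hochberg adjusted p up to 0.150 over the 4). Proximal tubule markers (1 of 31 higher, 30 not passing), loop of Henle and distal tubule markers (1 of 20 lower, 19 not passing) and erythroid markers (none of 11) did not pass as lists (limma's camera, Benjamini-Hochberg adjusted p = 0.506, 0.991 and 0.758), the first with 0.0126 without knockout replicate 3. The called members were Lrp2, the endocytic receptor megalin, at 0.91 ± 0.22, and Wnk4, a kinase of distal salt transport, at -0.57 ± 0.11 on the log2 scale (SE). The call for Lrp2 was lost without any heterozygous library or without knockout replicate 2, and that for Wnk4 without knockout replicate 2 (edgeR, Benjamini-Hochberg adjusted p up to 0.194 and 0.0556).

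**Figure D3:**
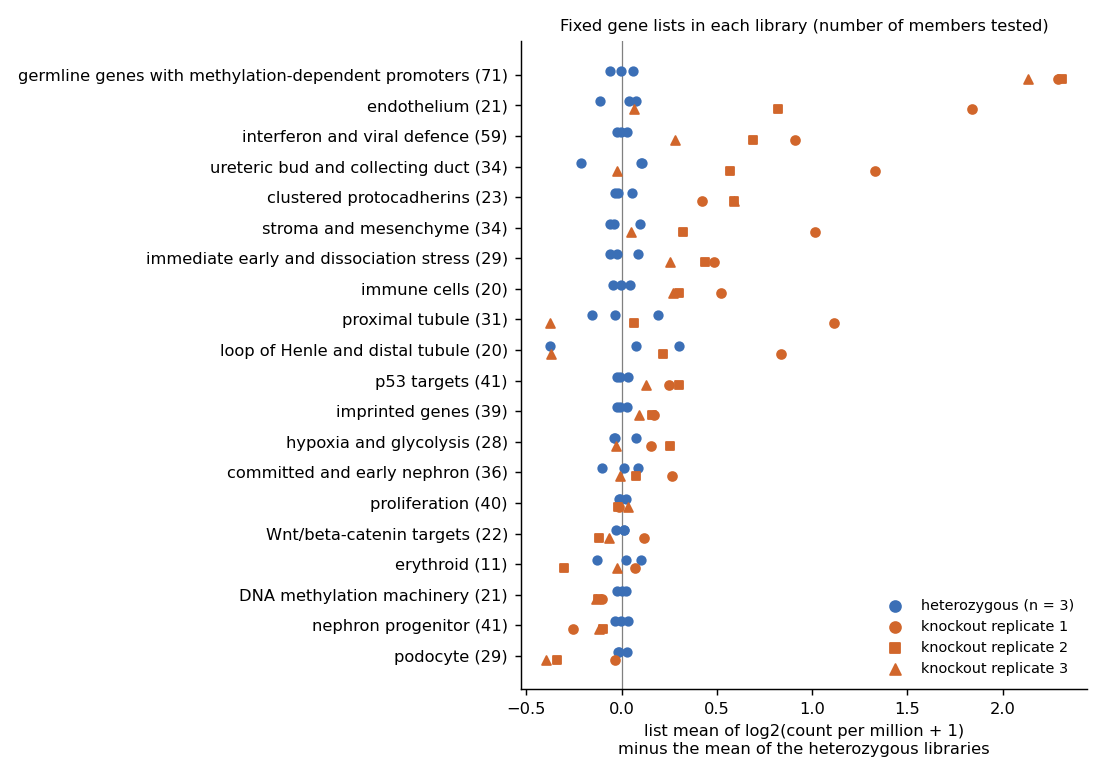
Mean log2(CPM + 1) of each fixed list in each library, minus the mean of the 3 heterozygous libraries (horizontal axis); circles in blue are heterozygous libraries and the 3 orange symbols are knockout replicates 1 to 3. Germline genes sit together in all 3 knockout libraries (3.08, 3.10 and 2.92 before subtraction), while endothelium (3.94, 2.92 and 2.16) and collecting duct markers (3.40, 2.63 and 2.04) spread with replicate 1 highest.

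Imprinted genes, expressed from 1 parental allele under the control of methylated regions, changed in both directions. Of 39 members tested, 5 rose, 4 fell and 30 did not pass (6 and 6 adjusted over the list alone). The list did not pass (limma's camera, Benjamini-Hochberg adjusted p = 0.973). Igf2, a fetal growth factor, fell from 636 ± 42.5 to 231 ± 23.5 CPM and Grb10, an inhibitor of growth signalling, from 1355 ± 53.03 to 631 ± 77.4 CPM (SD, n = 3 each). Their log2 fold changes were -1.46 ± 0.10 and -1.10 ± 0.10 (SE; edgeR, Benjamini-Hochberg adjusted p = 5.76e-06 and 7.65e-05). Phlda2, a growth-restricting gene of the placenta, rose 31.2-fold from 0.335 ± 0.156 to 10.4 ± 1.59 CPM, and Slc38a4, an amino acid transporter, rose by 0.55 ± 0.08 on the log2 scale (SE). The clustered protocadherins are cell adhesion genes each driven by its own promoter. Only 24 of the 58 fixed members could be matched to a gene, so the result does not cover the rest. Of 23 tested, 7 rose, none fell and 16 did not pass (12 rose when adjusted over the list alone). The median log2 fold change was 0.73 (limma's camera, Benjamini-Hochberg adjusted p = 0.00114, and adjusted p = 0.603 with an estimated correlation). Pcdhb11 rose from 7.19 ± 0.302 to 17.7 ± 0.457 CPM and Pcdhb14 from 7.56 ± 0.945 to 19.5 ± 3.44 CPM (SD, n = 3 each), and the division of reads among these similar genes is uncertain.

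Among the protein-coding genes that fell most by the naming rule, only Cntn3 went to nearly 0. Cntn3, a neural cell adhesion molecule on chromosome 6, fell from 10.6 ± 2.56 CPM to 0.0131 ± 0.0227 CPM (SD, n = 3 each), with a count ratio of 0.00149 and a 95% counting interval of 0.000151 to 0.0045 (edgeR, Benjamini-Hochberg adjusted p = 2.43e-06). Next came R3hdml (-2.42 ± 0.43 on the log2 scale, SE), Rit2, a small GTPase (-2.36 ± 0.34), Ctf2, a cardiotrophin (-2.05 ± 0.31), and Adamtsl3 (-2.05 ± 0.34). Tac2, a tachykinin, Cysltr1, a leukotriene receptor on chromosome X, and Slc26a7, an anion exchanger, had log2 fold changes of -1.90 ± 0.38, -1.76 ± 0.26 and -1.60 ± 0.21 (SE). The call for Tac2 was lost without heterozygous replicate 3 or knockout replicate 2 (edgeR, Benjamini-Hochberg adjusted p up to 0.0762). Slc26a7 was the most abundant of the 8, at 38.7 ± 6.90 CPM in the heterozygous and 12.7 ± 3.29 CPM in the knockout libraries (SD, n = 3 each).

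Single transcripts of some genes rose to very high levels while the other transcripts of the gene stayed far lower. Ccrn4l, the circadian deadenylase gene also called nocturnin, took 3.20%, 3.58% and 3.57% of all gene-paired counts in knockout replicates 1 to 3, the highest share of any gene there. Nearly all of this was 1 retained-intron transcript, whose estimated counts went from a mean of 18000 to a mean of 1840000 per library (log2 fold change 6.77 ± 0.16, SE; edgeR, Benjamini-Hochberg adjusted p = 7.49e-06), whereas the other transcripts of Ccrn4l together had means of 10.8 and 47.2 counts. The leading transcript of Wdr31 had means of 7090 and 844000 counts and its other 8 transcripts together 510 and 533. That of Slc38a6 had 10200 and 887000 and a second one 1180 and 154000. Its 6 remaining transcripts together had 510 and 1350, and 1 of these, also repeat-containing, went from 114 to 939. Counted over all 50137 transcripts tested, 795 were higher and 100 lower in the knockout (edgeR quasi-likelihood test at a Benjamini-Hochberg adjusted p of 0.05). Transcripts in which at least 10% of sampled 31-mers occurred 10 or more times in the genome held 7.48 ± 0.255% of gene-paired counts in the heterozygous and 15.7 ± 0.875% in the knockout libraries (SD, n = 3 each). Kallisto divides reads between transcripts that share sequence, so the fold change of such a transcript need not be that of its gene. The higher transcripts numbered 445, 363 and 488 without knockout replicates 1 to 3. The lower ones numbered 56, 37 and 38 without heterozygous replicates 1 to 3 and 65, 40 and 57 without knockout replicates 1 to 3.

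**Figure D4:**
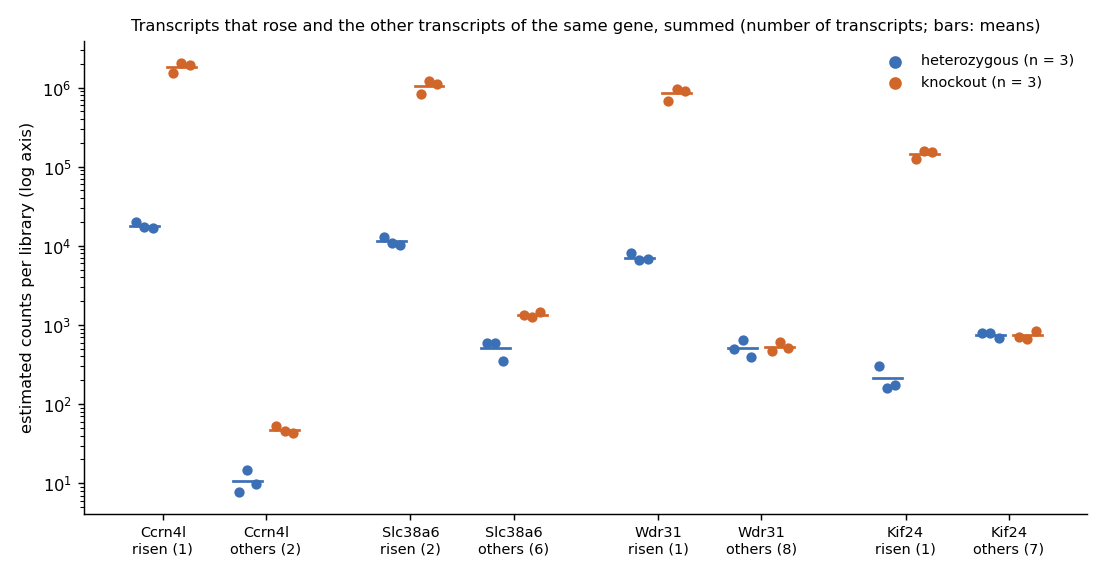
Estimated counts per library on a log axis for the transcripts of Ccrn4l, Slc38a6, Wdr31 and Kif24 that rose, and for the other transcripts of the same gene summed, with the 3 heterozygous libraries in blue, the 3 knockout libraries in orange and group means as bars. The Ccrn4l transcript goes from a mean of 18000 to 1840000 counts, while the other 7 Kif24 transcripts together stay at 755 and 740.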

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

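Of the tests in this part, the one on reads shared between copies of multicopy families and the counts over other splits of the samples were chosen before their results were seen, and all others after. Among 8831 transcripts that could not be paired with a gene, data outside the gene comparison, 188 were higher in the knockout and 7 lower (edgeR quasi-likelihood test at a Benjamini-Hochberg adjusted p of 0.05), 2.13% higher against 1.47% of the 41306 paired transcripts. The one with the most counts went from a mean of 4232 to 453321 estimated counts per library (log2 fold change 6.84 ± 0.20, SE).

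In all, 21 transcripts of 20 genes rose over 8-fold to at least 10000 counts in the knockout, Ccrn4l, Slc38a6 and Wdr31 among them. At least 10% repeated sequence was found in 16 of the 21, against 61 of 669 other transcripts as abundant (odds ratio 31.9, 1-sided Fisher's exact p = 1.68e-12), so reads from repeat copies elsewhere in the genome may account for these 16. The tables argue against transcription of the whole host gene for this part: in the 11 host genes with other measured transcripts, of 15, those had a median log2 ratio of -0.027 (quartiles -0.17 to 0.778) against 6.75 for the risen transcripts. Of the 5 genes under 10% repeated sequence, Dazl and Tuba3a had 0 other transcripts in the files. Their risen transcript is the whole gene as measured here, and 0% of its sampled 31-mers were repeated. For the 3 with other transcripts the question stays open. Those had a median of 10.19 with Tulp4 at -0.40, and Zscan4f and Zscan4c are multicopy genes. Which repeat family the sequences belong to was not tested, and a rise of repeat RNA in the knockout stays a hypothesis.

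Endothelium, collecting duct and stroma markers had their highest means in knockout replicate 1. Of 89 members, 67 had the order replicate 1 over 2 over 3 among the knockout libraries. That order was read from these same genes, so the count does not test it, and whether unequal numbers of cells of other types came through the sort stays open. A lower share of cap mesenchyme that raises every other cell type alike, red cells included, is argued against by 11 erythroid markers. Their median log2 fold change was -0.175 and their upper quartile 0.167, below the lower quartile of endothelium at 0.993. They do not bear on other kidney cells, whose lists had medians above 0 (proximal tubule 0.752, immune cells 0.605, stroma 0.552, loop of Henle and distal tubule 0.398). A lower share of cap mesenchyme without a rise of red cells therefore stays open. A change in every knockout library stays open, since in replicate 3 alone 28 of the 89 lay above all heterozygous libraries, where chance gives 22.2, and 21 did so in all 3, where chance gives 4.45. Chance is a low baseline, because over all tested genes the groups did not overlap, in either direction, for 29%, where chance gives 10%. The means of knockout replicate 3 for these 3 lists lay within the range of the heterozygous libraries. Without knockout replicate 1 there were 739 higher and 230 lower genes.

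Genes on chromosome X made up 101 of the 836 higher genes and 23 of the 327 lower genes. Different numbers of male and female embryos in the groups are argued against by the comparison with sex as a covariate, where 98 of 722 genes on chromosome X were higher against 544 of 16267 elsewhere (odds ratio 4.54, 1-sided Fisher's exact p = 3.48e-29 over genes, which are not independent). Reads shared between near-identical copies are argued against as the whole cause, since among single-copy genes 50 of 593 on chromosome X were higher against 614 of 14932 elsewhere (odds ratio 2.15, 1-sided Fisher's exact p = 3.56e-06), though the odds ratio over all genes was 3.44. Loss of methylation at promoters on chromosome X is a hypothesis that expression values do not test.

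Groups of 3 against 3 allow 10 splits, too few for a share under 0.05. The real split gave 1163 genes against at most 3 in the others, with 1 of the 10 splits as large. It gave 895 transcripts against at most 5, with 1 of 10 as large, and 8 lists against at most 12, with 8 of 10 as large.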

How the results depend on the processing

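Sex as a covariate and the removal of repeat-containing transcripts were tests chosen after the results were seen, and all other alternatives were planned. Against 836 genes higher in the knockout, DESeq2 gave 1346, log2(TPM + 1) 442, log2(TPM + 0.1) 436 and log2(TPM + 1) with no filter 542, and leaving out 1 library gave 526 to 916. Against 327 lower, library totals gave 1883, DESeq2 586, log2(TPM + 1) 660, log2(TPM + 0.1) 646 and sex as a covariate 162, and leaving out 1 library gave 116 to 272. Log2(TPM + 0.1) put 40.3% of calls higher against 71.9%. With an estimated correlation 1 gene list was higher and 0 were lower, and leaving out 1 library gave 4 to 10 higher and 1 to 2 lower lists. Under fry, which asks another question, the interferon, nephron progenitor, podocyte, collecting duct and endothelium lists lost their calls (adjusted p = 0.0593, 0.0719, 0.137, 0.216 and 0.26), and immune cells (0.0478, higher) and DNA methylation machinery (0.0341, lower) gained one. Without 1 library, 363 to 602 transcripts were higher and 37 to 65 lower. Leaving out a library tests fewer samples, and for the other alternatives the cause was not tested.

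Dnmt3a, not called, reversed to 0.076 with the transcript length offset, and Dnmt3b, not called, to -0.045 with library totals, -0.07 with log2(TPM + 1) with and without the filter and -0.096 with log2(TPM + 0.1). Over 71 named genes that were called, Dnmt1 left out, 1404 of 1542 alternative values kept the direction and call and 138 lost the call. Over 32 that were not called, 645 of 685 stayed so, 35 gained a call and 5 reversed. Of the 72 called with Dnmt1, 47 kept the call without each library and 25 lost it without at least 1. Over the 8 called lists 84 of 104 alternative values kept the call and 20 lost it, and over the 12 others 146 of 156 stayed uncalled and 10 gained a call.

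With the replicate number as a block, 200 transcripts were higher and 12 lower, against 795 and 100, and 892 of 1163 gene calls were kept with none of opposite sign. The collecting duct list lost its call (adjusted p = 0.0628, limma's camera). The labels do not say what the numbers mean. Libraries with the same number had correlations of deviations of -0.068, -0.031 and -0.045, and those with different numbers -0.114 to 0.135. No pairing was seen, but so few libraries cannot exclude a shared litter or batch. Without repeat-containing transcripts 735 genes were higher and 313 lower, against 836 and 327. Of the 1163 gene calls only 1087 could still be tested, of which 1038 were kept and 6 had the opposite sign. Depth limits genes under about 0.069 CPM, where 3 counts lie in the shallowest library.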

Other observations

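Of the tests in this part, the one on promoter CpG was chosen before its result was seen, and its repeat over single-copy genes and the one on Hox genes after. A hypothesis is that Hox genes are lower as a family in the knockout, beyond the members of the nephron progenitor list that prompted the test. Of 31 Hox genes tested outside that list, 10 fell, none rose and 22 had a log2 fold change below 0, with a median of -0.399, against 310 lower of 16917 other genes outside it (1-sided Fisher's exact p = 1.56e-10 over genes, which are not independent). The called genes included Hoxa5 (-0.98), Hoxa9 (-0.61), Hoxd4 (-0.84), Hoxc6 (-0.78) and Hoxb3 (-0.59 on the log2 scale). Hoxb3 was the only Hoxb gene called. Hoxb7 (0.10), Hoxb8 (0.65) and Hoxb9 (0.10) lay above 0, and the other Hoxb genes below it. The median of the Hox genes outside the list was -0.549 under library totals and -0.484 under TPM. These scalings also lowered the median of all tested genes, to -0.161 and -0.126. A Hox median that stayed below 0 under them is therefore no added support. A change in the cells sampled could lower these genes as well, and this was not tested.

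Other genes changed by large ratios, chosen here after their values were seen and not tested as a list. Zscan4f was at 0.408 CPM in the heterozygous and 408 CPM in the knockout group and Zscan4c at 0.193 and 254 CPM, with the same uncertainty among near-identical copies. Dux was at least 13.6-fold higher but reached only 0.795 CPM in the knockout, and Zfp352 reached 0.962 CPM, with a count ratio of 148 and a 95% counting interval of 26.2 to 5900. Among genes that fell, Lrrfip2 was at least 9.13-fold lower and Ccl27b had a count ratio of 0.0436 with a 95% counting interval of 0.00446 to 0.143. Lrrfip2 had 59.8, 13.8 and 11.1 estimated counts in heterozygous replicates 1 to 3, so replicate 1 carried much of that bound.

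A hypothesis is that the genes switched on in the knockout have promoters with more CpG sites, the sites that Dnmt1 methylates, than genes that stayed silent. The median observed over expected CpG ratio around the annotated 5' end was 0.299 over 159 genes switched on and 0.149 over 5650 genes silent in both groups, a difference of 0.149 (2-sided permutation p = 1e-05, the smallest that 100000 permutations can give, over genes, which are not independent). Some of the 159 are near-identical copies; over 84 and 4194 single-copy genes the medians were 0.309 and 0.156. Over protein-coding genes the medians were 0.324 and 0.144. This is consistent with the hypothesis, but methylation itself was not analysed here, and genes that differ in CpG content may differ in other ways.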
